A study of Homo sapiens with 6 samples.

How the data were processed

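Total RNA of 6 samples was hybridised to Affymetrix arrays after biotin labelling, per the labels' protocols, with 1 array per sample. The sample titles name TPC-1 cells with control shRNA or FAM60A shRNA and a replicate number from 1 to 3, and samples were grouped by these titles into 3 arrays labelled control shRNA and 3 labelled FAM60A shRNA. The RNA extraction protocol names DLD1 in place of TPC-1.

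The deposited values were log2 expression values, 1 table of 49395 probe sets by 6 arrays with 0 missing values, which the authors made with RMA per the submitters' processing notes. RMA subtracts background, quantile normalizes the arrays and summarises the probes of a probe set. The program, its version and the chip description are not given in the sources used here. The deposited values had further been centred, since the median of each probe set over the 6 arrays was 0 to within 5e-07, so that a value is a difference from that median. The base of the logarithm is not stated in the table and was taken as 2 because RMA gives log2 values. Array medians lay between -0.015 and 0.010. Centring leaves differences between arrays as they were and removes the expression level except for the coarse class described below, where it can be read, and a finer level is needed to filter dim probe sets by mean level or to bound a difference by background. The precision of a difference is limited by the number of arrays.

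Probe sets were named from the platform annotation. Of the probe sets, 44994 had 1 gene symbol, 1832 had several and were not named, and 2569 had none. Symbols were checked through Entrez identifiers against a RefSeq table of assembly GRCh38.p14, used for names only, which changed 0 symbols. Of 744 gene entries of the lists below, 2 were matched by an older symbol and 48 genes were not analysed here. The 102 control probe sets were left out of the tests of genes.

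The mean of a gene's probe sets with 1 symbol stood for the gene, giving 18132 genes. The plan fixed before the data were examined was to take the probe set with the highest mean level, which centred values do not give, so the mean, listed beforehand as another rule, took its place. Among 11735 genes with several probe sets, 435 had probe sets past the threshold in both directions, and 169 genes past the threshold had a probe set past it in the opposite direction.

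Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the log2 values with no further normalization, and p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Differences are arrays labelled FAM60A shRNA minus arrays labelled control shRNA. SINHCAF and the RNA quality measures were also tested with two-sided exact permutation tests, whose smallest p with 3 against 3 arrays is 0.1. The 29 gene lists were fixed before the data were examined and tested two-sided with limma's camera at a preset correlation of 0.01, adjusted over the lists. Members were counted past the threshold over all genes and adjusted over the list alone. Intestinal markers were among the lists because the extraction protocol names DLD1.

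The rule for named genes, fixed before the data were examined, took SINHCAF, then the 12 genes with the largest positive and the 12 with the largest negative log2 difference among those past the threshold without overlap between the groups, up to 4 members per list with the smallest p, the SIN3-HDAC list, and CCND1, CDKN1A, TGFBR2, CDH1, VIM, MKI67 and PAX8, with 1 more gene that is not reported here. Its further condition on the level could not be applied to centred values. Other list members that the text names, and SRP14, were chosen after their values were seen.

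Level classes were worked out after the data were seen. Deposited values carry the rounding of single-precision numbers, whose step doubles at levels of 2, 4, 8 and 16, so the step shared by the values of a probe set gives the class of its level before centring. On simulated values 98.4%, 98.4% and 98.2% of probe sets with levels from 2, 4 and 8 came out in their class. Among the deposited probe sets, 11254 had the step of a level of 8 to 16, 24300 of 4 to 8 and 12905 of 2 to 4, while 161 were unresolved, 67 of them because fewer than 4 of their values lay under 1, where the step can be read, and 94 because no step fitted their values. A large change thus hides the class. Another 775 had the step of a level of 16 or more, above what RMA gives, and were counted with the class of 8 to 16. If these were misplaced from that class, 6.44% of its probe sets came out 1 class too high, against 1.84% in the simulation, so the simulation understates the error of the classes. Of 17 control tags without a target, 16 fell in the class of 2 to 4, and 9 of 9 hybridisation controls fell in that of 8 to 16.

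The fit was tested on simulated data for 18132 genes in 3 against 3 arrays. Of 50 genes changed by each log2 difference, it called 62% at 0.25, 88% at 0.5, 98% at 1 and 100% at 2, and it called 7 of 17932 unchanged genes. A simulated list lowered by 0.2, the G2/M list, was called and 0 of 28 other lists were. Genes were simulated as independent of each other, and most or all others were left unchanged. In the data the estimated correlation of the G2/M list was 0.15 and 44.9% of genes passed. These rates therefore do not give the error of the calls in the data. Alternatives were the replicate number as a block, 3 other normalizations, other rules for probe sets, robust and weighted fits, Welch's test per gene, a threshold of 0.01, other set tests, leaving out each array, and filters on level class added after the data were seen.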

Results

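Gene expression was profiled in cells labelled TPC-1, a human cell line from papillary thyroid carcinoma. They are described as infected with a lentivirus carrying an shRNA against FAM60A or a control shRNA. FAM60A is the older symbol of SINHCAF, a subunit of the SIN3-HDAC complex, a co-repressor that removes acetyl groups from histones. RNA of 3 samples labelled FAM60A shRNA and 3 labelled control shRNA was hybridised to Affymetrix arrays, 1 array per sample, and the design asks which transcripts differ when FAM60A is targeted. Every sample title and cell line label names TPC-1, whereas the protocol for RNA extraction names DLD1, a human colorectal cancer line. The design describes the samples of a group as independent and says nothing of separate cultures, so p-values measure the spread between these samples, which can be technical. The number of arrays limits the precision. The values were log2 expression values of 49395 probe sets, each set relative to its own median over the 6 arrays, so they give differences between arrays and of the expression level at most a coarse class, which 161 probe sets lack, among them all those of the 12 genes with the largest rise. Averaging the probe sets of a gene gave 18132 genes.

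SINHCAF, the gene that the shRNA names, was higher in the arrays labelled FAM60A shRNA, against the direction that the labels give. Its log2 value relative to the median was 0.60 ± 0.032 (SD, n = 3) in the arrays labelled FAM60A shRNA and -0.64 ± 0.050 (SD, n = 3) in the arrays labelled control shRNA. The log2 difference of 1.24 (SE 0.038) is a 2.36-fold higher signal, with a 95% confidence interval of 2.22 to 2.51 (limma, adjusted p = 1.09e-06). The 3 values of one group did not overlap with the 3 of the other, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. SINHCAF (Entrez gene 58516) lies on chromosome 12 and is measured by 3 probe sets, with log2 differences of 1.24, 1.31 and 1.17. Because the targeted gene runs against the labels, groups are called "arrays labelled FAM60A shRNA" and "arrays labelled control shRNA" below, and each rise or fall is one in the former relative to the latter, not one that follows a measured loss of SINHCAF.

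**Figure D1:**
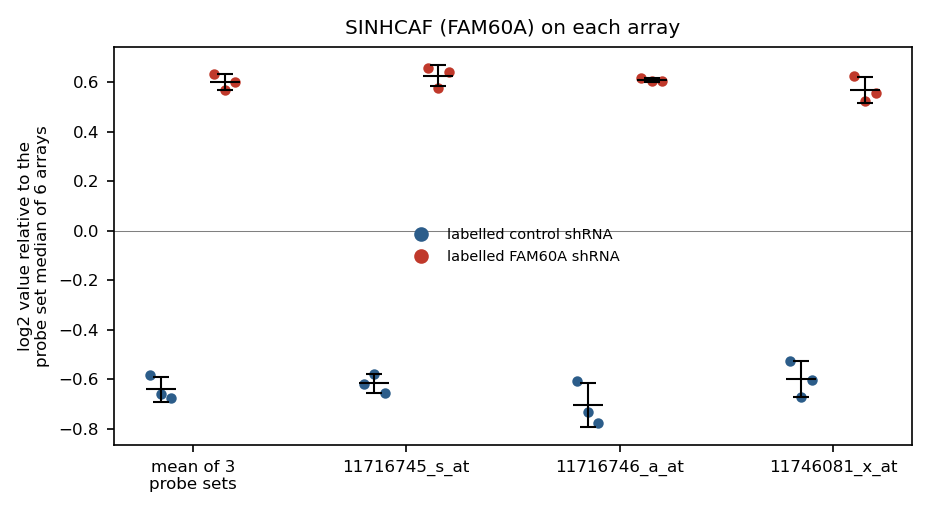
Log2 values of SINHCAF relative to the probe set median over 6 arrays (vertical axis), as the mean of its 3 probe sets and for each probe set (horizontal axis). Points are arrays and bars are the mean ± SD of 3 arrays; for the gene the arrays labelled FAM60A shRNA lie around 0.60 and those labelled control shRNA around -0.64.

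A calcium-binding protein, a stress-response gene and a pair of chemokines rose most in the arrays labelled FAM60A shRNA. S100P, the calcium-binding protein, was 11.7-fold higher with a log2 difference of 3.55 ± 0.051 (SE, n = 3 per group), and DDIT4, a stress-induced inhibitor of mTORC1, was 8.04-fold higher with 3.01 ± 0.050. The chemokines CCL20 and CXCL3 were 7.61-fold and 7.15-fold higher, with log2 differences of 2.93 ± 0.036 and 2.84 ± 0.036. The largest fall was that of MYBL1, a transcription factor of the MYB family, which was 4.28-fold lower with a log2 difference of -2.10 ± 0.062. MZT1, a component of the gamma-tubulin ring complex, followed at -1.63 ± 0.033. No level class is known for MYBL1 or for any of the 12 genes with the largest rise, so nothing here shows that their lower group lies above background, and their folds are those of the deposited values.

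The other 8 of the 12 genes with the largest rise were SEL1L3 (log2 difference 2.71), the secreted ligand BMP2 (2.60), the chitinase-like glycoprotein CHI3L1 (2.51), PRR15L (2.45), the calcium-binding protein S100A16 (2.43), EPS8L3 (2.37), the serine protease PRSS23 (2.34) and ELF3 (2.32), an epithelial ETS transcription factor. The other 10 of the 12 with the largest fall were BTF3L4 (-1.57), ALG5 (-1.51), a glucosyltransferase of N-glycosylation, ENPP5 (-1.44), KLHL28 (-1.42), RGS2 (-1.41), a regulator of G-protein signalling, the sorting nexin SNX16 (-1.41), the centrosomal protein CEP97 (-1.40), IER3IP1 (-1.37), the neuronal serpin SERPINI1 (-1.34) and the homeobox gene MNX1 (-1.31). Probe sets differed in size for SNX16 (-2.03 to -0.43), IER3IP1 (-1.96 and -0.77) and MZT1 (-2.07 to -0.86), though all passed. The SE of a gene measures the spread between arrays and not that between probe sets. These 24 genes were chosen for an adjusted p under 0.05 and no overlap between the labels, so neither trait is a finding about them. The largest adjusted p among them was 6.14e-06, that of MNX1 (limma).

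**Figure D2:**
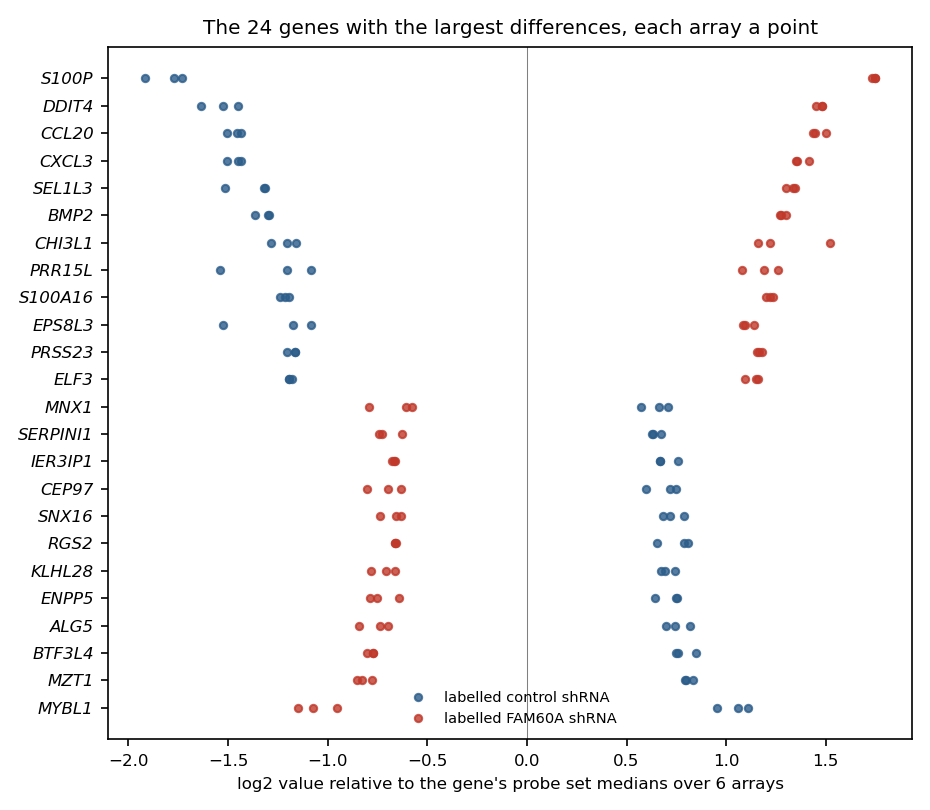
Log2 values relative to the probe set medians over 6 arrays (horizontal axis) for the 12 genes with the largest rise and the 12 with the largest fall in the arrays labelled FAM60A shRNA (vertical axis), each array a point. In each gene the 3 arrays of one label lie on one side of 0 and the 3 of the other label on the other side. The choice of genes without overlap and the centring on medians bring this about. Log2 differences run from 3.55 for S100P to -2.10 for MYBL1.

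In all, 8136 of 18132 genes (44.9%) differed between the labels at an adjusted p under 0.05 (limma, n = 3 per group). Of these, 3595 were higher and 4541 lower in the arrays labelled FAM60A shRNA, and their median absolute log2 difference was 0.30. The excess of lower genes was not kept by every scaling, with 3929 higher and 4183 lower after another quantile normalization and 4063 and 4049 after cyclic loess. A change of at least 2-fold was seen in 270 genes, 217 higher and 53 lower, and of at least 4-fold in 22 higher genes and 1 lower gene, MYBL1. With the arrays quantile normalized again, the genes that changed at least 2-fold were 167 higher and 96 lower. With the probe set of largest variance for each gene they were 648, 443 higher and 205 lower, and with any probe set past the threshold 591, 412 higher and 179 lower. The groups did not overlap in 9642 genes (53.2%), where chance gives 10% for 3 against 3. The median log2 difference of all genes was -0.012, and the median SE of a gene's difference was 0.044.

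Genes of the amino acid response, which the transcription factor ATF4 induces when amino acids run short, rose in the arrays labelled FAM60A shRNA. Of 22 measured, 19 rose, 0 fell and 3 did not pass the test, with 19 past it when adjusted over the list alone. DDIT4 led, followed by MTHFD2 (log2 difference 1.07), an enzyme of mitochondrial folate metabolism, PHGDH (0.86), the first enzyme of serine synthesis, and asparagine synthetase ASNS (0.79). The list median was 0.60 (camera, adjusted p = 1.05e-10; adjusted p = 0.061 with an estimated correlation). Of 21 genes of endoplasmic reticulum stress and the unfolded protein response, 11 rose and 4 fell, 15 in all when adjusted over the list alone, with a median of 0.13. The chaperones HSPA5 (0.99) and HYOU1 (1.04), the transcription factor XBP1 (0.80) and HERPUD1 (0.75) rose, whereas the stress sensor ATF6 (-0.22) fell (adjusted p = 0.0097; adjusted p = 0.36 with an estimated correlation). Of 16 antioxidant genes that NRF2 controls, 11 rose and 2 fell, 13 when adjusted over the list alone, with a median of 0.39. NQO1 (1.22), HMOX1 (1.20), which breaks down haem, ME1 (0.83) and TKT (0.73) rose, and the 2 that fell were SRXN1 (-0.60) and GCLM (-0.48) (adjusted p = 1.90e-04; adjusted p = 0.061 with an estimated correlation).

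Inflammatory cytokine and NF-kB target genes, some chemokines among them, rose as a list with the same label. Of 25 cytokine and NF-kB target genes, 14 rose and 1 fell over all genes, and 17 passed when adjusted over the list alone, with a median of 0.23. CCL20 and CXCL3 were followed by CXCL2 (1.84), CXCL5 (1.53), CXCL8 (1.27) and CXCL1 (1.21), and the gene that fell was NFKB2 (-0.17) (camera, adjusted p = 2.52e-06; adjusted p = 0.054 with an estimated correlation). TNF (0.02), IL1A (0.04) and IL6 (0.11) did not pass. Of 34 interferon-stimulated genes, 12 rose and 5 fell, 17 when adjusted over the list alone, and the list did not pass (adjusted p = 0.20). ISG20 (0.89) and OAS1 (0.85) rose and IFIT1 (-0.69) fell.

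Wnt target genes rose in the arrays labelled FAM60A shRNA, as did genes of the TGF-beta pathway and its targets. Of 21 Wnt/beta-catenin target genes, 17 rose and 1 fell, 18 when adjusted over the list alone, and their median log2 difference of 0.73 was the highest of the 29 lists (camera, adjusted p = 2.62e-08; adjusted p = 0.061 with an estimated correlation). ASCL2 was 4.60-fold and LGR5, a receptor of intestinal stem cells, 3.99-fold higher. MYC (1.68), NKD2 (1.33), RNF43 (1.19) and AXIN2 (1.07) also rose, TROAP (-0.29) fell, and CCND1, which encodes cyclin D1, had a log2 difference of -0.06 and did not pass (adjusted p = 0.15). Of 33 genes of the TGF-beta pathway and its targets, 22 rose and 5 fell, 27 when adjusted over the list alone, with a median of 0.25 (adjusted p = 1.13e-05; adjusted p = 0.054 with an estimated correlation). The members with the largest rise were BMP2 (2.60) and ID1 (2.01), followed by ID3 (1.53), BAMBI (1.39) and PMEPA1 (1.24). ID1 and ID3 are known targets of BMP signalling. TGFBR2, the type II receptor of TGF-beta, had a log2 difference of -0.14 and did not pass (adjusted p = 0.10).

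Markers of intestinal epithelium also rose in the arrays labelled FAM60A shRNA. Of 18 measured, 10 rose and 1 fell, 12 when adjusted over the list alone, with a median log2 difference of 0.18 (camera, adjusted p = 2.20e-04; adjusted p = 0.061 with an estimated correlation). With only the probe sets of the highest level class, a filter chosen after the data were seen, 5 of the 18 genes were left, without ASCL2, which has no level class, 4 higher and 1 lower with a median of 0.83, and the list did not pass (adjusted p = 0.051). For the full list, 11 genes rose and 0 fell under each of the 3 other normalizations, so its 1 fall depended on the scaling. The genes that rose included the intestinal homeobox factor CDX2 (1.0), KRT20 (1.20), TFF1 (1.20), the intestinal cadherin CDH17 (0.82) and ASCL2, which also belongs to the Wnt list. Of 28 epithelial junction and keratin genes, 17 rose and 3 fell, 20 when adjusted over the list alone, with a median of 0.28 (adjusted p = 3.99e-05; adjusted p = 0.20 with an estimated correlation). The claudins CLDN4 (1.41) and CLDN7 (0.94), KRT7 (1.18), TJP3 (1.07) and the splicing factor ESRP1 (0.88) rose, and CLDN1 (-0.91), CRB3 (-0.28) and OCLN (-0.26) fell. CDH1, which encodes E-cadherin, rose by 0.14 and lost its call without the second array labelled FAM60A shRNA, where its log2 difference was 0.13. Of 35 mesenchymal and matrix genes, 8 rose and 5 fell, 13 when adjusted over the list alone, and the list did not pass (adjusted p = 0.71). COL4A2 (0.57) rose, and ITGB1 (-0.54), ZEB1 (-0.49) and VIM (-0.19) fell. Of their probe sets, 5 of 7 of ZEB1 and 1 of 2 of VIM lay in the lowest level class, which holds 16 of 17 control tags without a target, and without that class, a filter chosen after the data were seen, the differences were -0.84 and -0.14. The fall of VIM lost its call when any 1 of the arrays labelled control shRNA was left out, with log2 differences from -0.21 to -0.17.

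Of 20 thyroid differentiation genes, 0 rose and 3 fell, also 3 when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.54). HHEX (-0.97), a homeobox factor of the thyroid bud, TFF3 (-0.22) and GLIS3 (-0.18) fell. PAX8, a transcription factor that thyroid follicular cells need, had a log2 difference of -0.08 (adjusted p = 0.20), thyroglobulin TG had -0.13 (adjusted p = 0.097), and neither passed. Only 3 of the 20 genes had a probe set in the level class of 8 or more. PAX8 and TG had 0 there, and 1 of 4 and 1 of 3 of their probe sets lay in the lowest class. A gene near background cannot show a fall, so these values do not show that thyroid genes were unchanged. Of 19 leukocyte markers, 2 rose, CD68 (0.26) and CD79A (0.14), and 0 fell, with 1 past the test when adjusted over the list alone. CD79A lost its call without replicate 1 labelled control shRNA (0.12) and without replicate 2 (0.12) or replicate 3 (0.14) labelled FAM60A shRNA. Of 13 endothelial markers, 1 rose, EGFL7 (0.19), and 0 fell, also 1 when adjusted over the list alone. Neither the leukocyte (adjusted p = 0.54) nor the endothelial list (adjusted p = 0.65) passed.

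Genes of cholesterol synthesis rose in the arrays labelled FAM60A shRNA. Of 19 measured, 16 rose and 0 fell, and adjusted over the list alone 16 rose and 1 fell, with a median log2 difference of 0.35 (camera, adjusted p = 9.78e-07; adjusted p = 0.054 with an estimated correlation). INSIG1 (0.98), a sterol sensor, SREBF2 (0.79), the transcription factor of the pathway, and the enzymes HMGCS1 (0.76) and LSS (0.69) led. Of 15 genes of fatty acid synthesis and desaturation, 6 rose and 2 fell, 9 when adjusted over the list alone, and the list did not pass (adjusted p = 0.20). SCD (1.26) and FASN (0.83) rose and ELOVL6 (-0.47) fell. Of 17 glycolysis enzymes, 8 rose and 4 fell, 14 when adjusted over the list alone, and the list did not pass (adjusted p = 0.38). PKM, which encodes pyruvate kinase M, was 4.85-fold higher with a log2 difference of 2.28 ± 0.034 (SE, n = 3 per group), and its 6 probe sets lay between 1.91 and 2.60. HK2 (0.40) rose, and ENO2 (-0.67) and HK1 (-0.40) fell. Of 27 hypoxia-induced genes, 11 rose and 6 fell, 20 when adjusted over the list alone, and the list did not pass in camera (adjusted p = 0.28), except without the probe sets named x_at or s_at (adjusted p = 0.044). VEGFA (0.86) rose and BNIP3L (-0.52) fell.

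Subunits of oxidative phosphorylation fell in the arrays labelled FAM60A shRNA. Of 37 measured, 26 fell and 2 rose, 31 when adjusted over the list alone, with a median log2 difference of -0.19 (camera, adjusted p = 1.05e-05; adjusted p = 0.062 with an estimated correlation). The complex I subunits NDUFC1 (-0.55), NDUFA2 (-0.43) and NDUFS7 (-0.39) fell. UQCRC2, a core subunit of complex III, rose instead by 1.68 ± 0.042 (SE, n = 3 per group), with its 2 probe sets at 1.54 and 1.82, and NDUFV2 rose by 0.14. Of 35 cytosolic ribosomal proteins, 13 rose and 0 fell, also 13 when adjusted over the list alone, with a median of 0.051 (adjusted p = 0.0034; adjusted p = 0.29 with an estimated correlation). The size of this small median depended on the scaling. It was 0.070 after another quantile normalization, with 16 higher, and 0.078 after cyclic loess, with 17 higher. RPL3 (0.48), RPS16 (0.31) and RPS2 (0.27) rose most. The 3 probe sets of RPL3 ran from 0.24 to 0.71 and all passed. Those of RPS16 lay at 0.017 and 0.60 and those of RPS2 at 0.036 and 0.50, and 1 of 2 passed in each.

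Genes of G2 phase and mitosis fell as a group, while those of DNA replication went both ways. Of 39 G2/M and mitosis genes, 26 fell and 4 rose, 32 when adjusted over the list alone, with a median log2 difference of -0.20 (camera, adjusted p = 3.17e-05; adjusted p = 0.29 with an estimated correlation). NUF2 (-0.72) and NDC80 (-0.62) of the kinetochore, ANLN (-0.68), which acts in cytokinesis, BIRC5 (-0.67) and TOP2A (-0.54) fell. CCNB2 (0.84), the proliferation marker MKI67 (0.34), CDC20 (0.31) and KIF20A (0.15) rose. Of 39 genes of DNA replication and the G1/S transition, 16 rose and 14 fell, 32 when adjusted over the list alone, and the list did not pass (adjusted p = 0.54). MCM4 (0.64) and POLE2 (0.49) rose and MCM6 (-0.45) and E2F1 (-0.46) fell. Of 14 genes of D-type cyclins, their kinases and CDK inhibitors, 5 rose and 5 fell, also 10 when adjusted over the list alone (adjusted p = 0.74). The inhibitors CDKN1C (0.97) and CDKN1A (0.31) and the kinases CDK6 (0.47) and CDK4 (0.44) rose, and the inhibitor CDKN2D (-0.77) and CCND3 (-0.46) fell. Of 20 histone genes, 4 rose and 7 fell, 12 when adjusted over the list alone (adjusted p = 0.65), with H1-2 (0.43) higher and H2BC4 (-0.77) lower.

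The other subunits of the SIN3-HDAC complex changed in both directions. Of 20 measured, 6 rose and 6 fell, 14 when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.98). SAP30L (0.54), the scaffold SIN3A (0.51), FOXK1 (0.45), RBBP4 (0.23), SAP130 (0.14) and OGT (0.14) rose. MORF4L1 (-0.59), SAP30 (-0.58), ING2 (-0.46), the other scaffold SIN3B (-0.45), KDM5A (-0.38) and SUDS3 (-0.34) fell. The deacetylases HDAC1 (-0.09) and HDAC2 (0.07), and also RBBP7 (-0.12), BRMS1 (0.11), FOXK2 (0.03), ING1 (-0.02), ARID4B (0.01) and PHF12 (-0.0023), did not pass. The 4 probe sets of SAP30L disagreed, with log2 differences from -0.22 to 0.95, as did the 2 of RBBP4, at -0.048 and 0.52, and the 2 of FOXK2, at -0.29 and 0.36, which passed in opposite directions. The probe sets of OGT ran from -0.056 to 0.44, and those of HDAC1, HDAC2, ING1, ARID4B and PHF12 also differed in sign. Without the first array labelled control shRNA, HDAC1 passed (-0.14), as did RBBP7 (-0.15) and TGFBR2 (-0.19) without the first array labelled FAM60A shRNA.

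Lists of growth and death signalling held large changes in both directions and did not pass as groups. Of 23 p53 target genes, 9 rose and 8 fell, 18 when adjusted over the list alone (camera, adjusted p = 0.49). The stress cytokine GDF15 (2.16) and the pro-apoptotic genes PMAIP1 (1.26) and BBC3 (1.21) rose, and ZMAT3 (-0.61) and MDM2 (-0.36) fell. The 5 probe sets of GDF15 all passed but ran from 0.32 to 3.26. Of 32 apoptosis regulators, 11 rose and 11 fell, 23 when adjusted over the list alone (adjusted p = 0.70), with BIRC2 (-0.61) and DIABLO (-0.43) lower. Of 22 MAPK/ERK output genes, 5 rose and 9 fell, 15 when adjusted over the list alone (adjusted p = 0.98). MYC, PHLDA1 (0.82) and DUSP5 (0.81) rose, and EPHA2 (-0.63) and EGR1 (-0.60) fell. Of 20 YAP/TAZ target genes, 9 rose and 6 fell, 16 when adjusted over the list alone (adjusted p = 0.66), with ANKRD1 (1.18) and AJUBA (1.03) higher and CCN2 (-1.20) and AXL (-0.92) lower. Of 29 matrix-degrading proteases and their inhibitors, 9 rose and 5 fell, 14 when adjusted over the list alone (adjusted p = 0.16). MMP15 (0.91), TIMP4 (0.81) and PLAU (0.79) rose and PLAUR (-0.38) fell.

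**Figure D3:**
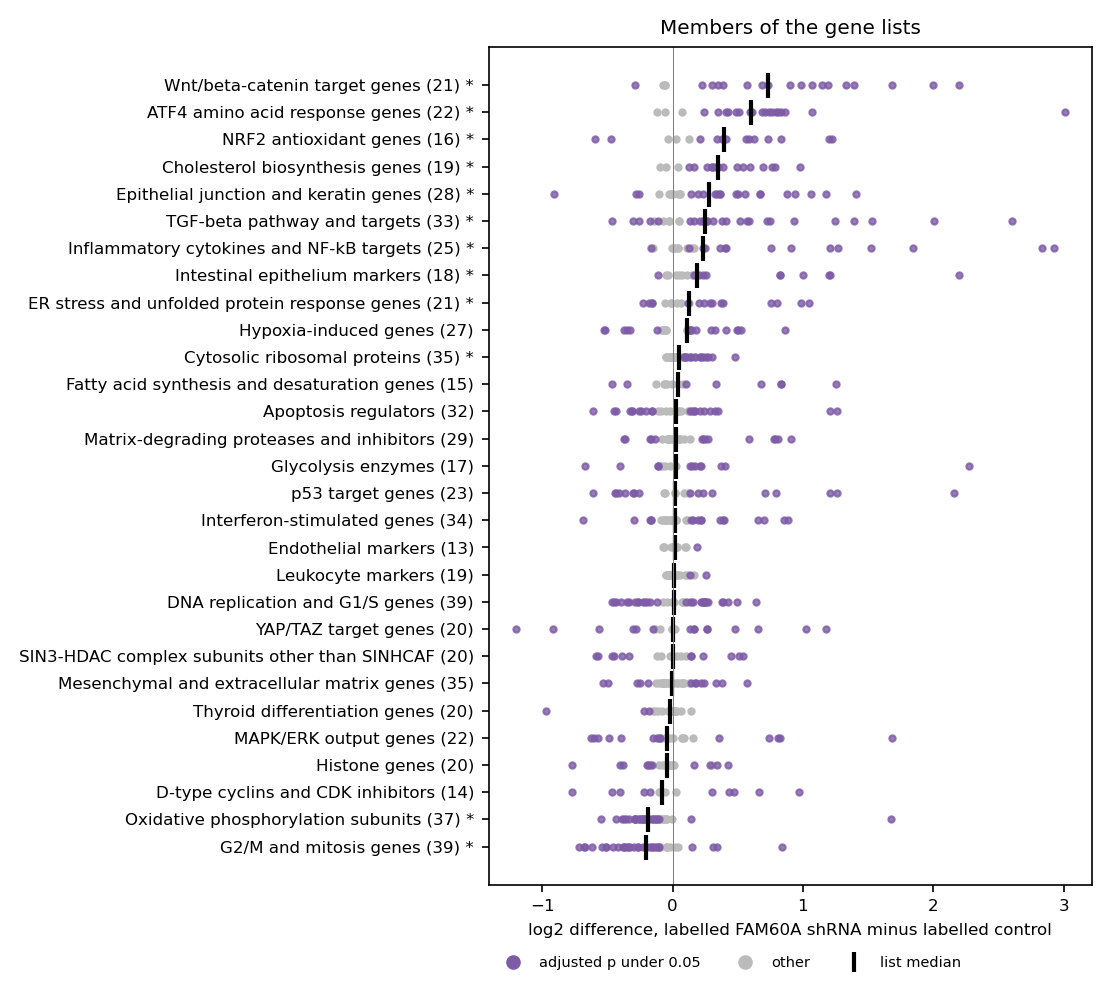
Log2 differences, arrays labelled FAM60A shRNA minus arrays labelled control shRNA (horizontal axis), of the measured members of 29 gene lists (vertical axis, number of members in brackets). Each point is a gene, coloured where its adjusted p was under 0.05, black bars are list medians, from 0.73 for Wnt target genes to -0.20 for G2/M genes, and stars mark the 12 lists past an adjusted p of 0.05 in camera.

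In all, 12 of the 29 lists passed at an adjusted p under 0.05 with camera's preset correlation, 10 higher and 2 lower, and 0 passed with an estimated correlation, where 8 had an unadjusted p under 0.05 and the smallest adjusted p was 0.054. Fry, which tests each list by itself and not against other genes, called 25. The signs of a list's median, mean and camera test differed in 4 lists that did not pass. The SIN3-HDAC list had a median of 0.0022 and a mean of -0.039, tested down, the D-type cyclin list -0.077 and 0.042, tested up, the MAPK/ERK list -0.041 and 0.067, tested down, and the mesenchymal list -0.0054 and 0.0067, tested up.

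Measures of RNA quality did not pass a test between the labels. The 3' minus 5' log2 signal of GAPDH differed by -0.012 between arrays labelled FAM60A shRNA and arrays labelled control shRNA (exact permutation p = 0.4, two-sided) and that of ACTB by -0.029 (exact permutation p = 0.3). The hybridisation controls, 9 probe sets for bacterial and phage transcripts, differed by 0.058 (exact permutation p = 0.2) and the 12 probe sets for polyA controls by 0.022 (exact permutation p = 0.5). Adjusted over these 4 measures, each p was 0.5, and 3 against 3 arrays cannot give a p under 0.1.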

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

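The result below comes from probe sets outside the comparison of genes. Among 2473 probe sets that are not controls and had no gene name here, 835 passed an adjusted p under 0.05 in limma, 371 higher and 464 lower in the arrays labelled FAM60A shRNA. The log2 differences farthest from 0 were 1.68 and -1.67. Their genes were not analysed here, and groups of 3 arrays were too small for a test of single arrays that stand apart.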

How the results depend on the processing

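The filters on level class were chosen after the data were seen, all other settings before. SINHCAF was higher in the arrays labelled FAM60A shRNA in every setting run, with log2 differences from 1.12 to 1.31 and adjusted p up to 9.15e-04 in limma or Welch's test with Benjamini-Hochberg adjustment. Without each array in turn the count of changed genes was 7366 to 7699 of 18132. Of the values of 154 named genes over all settings, 2 reversed, 25 lost their call and 29 gained one. A change of sign counted as a reversal only where the gene passed in that setting or in the main fit. Not every gene had a value in every setting, least of all with only the highest level class. The 12 lists that passed kept their call under the block, the normalizations, the rules for probe sets run on lists, array weights and without each array, and 1 more passed, the hypoxia list, without probe sets named x_at or s_at (adjusted p = 0.044).

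The genes lower at least 2-fold, 53 as reported, were 96 with quantile normalization again, and the cause was not tested. With the probe set of largest variance 648 genes changed at least 2-fold, 443 higher and 205 lower, and with all probe sets tested and any past 591, 412 and 179, against 270, 217 and 53, where both rules take 1 probe set of a gene by its variance or p in place of the mean. Camera with an estimated correlation called 0 lists, where 8 had an unadjusted p under 0.05, and fry 25. Fry gave the MAPK/ERK list (adjusted p = 0.00798) and the YAP/TAZ list (adjusted p = 0.00143) the direction opposite to camera's, where camera gave 0.49 to 0.99 and 0.36 to 0.75 over its settings. With only the highest level class, where 6610 genes were tested, 4961 genes changed, 2217 higher and 2744 lower, 4147 of them also changed in the same direction over all genes, and 164 changed at least 2-fold, 131 higher and 33 lower. That is 75.1% of the genes tested against 44.9%, where the filter changes both the genes tested and the probe sets averaged, and the cause was not tested. The counts at least 2-fold are not comparable, because a class is read from values under 1 and the change itself decides which probe sets have one. No probe set had a class in 23 of the 270 genes changed at least 2-fold and 20 of the 23 changed at least 4-fold, against 28 of all 18132 genes. There SAP30L (-0.22) and RBBP4 (-0.048) turned because other probe sets dropped out, and the intestinal list, with 5 of its 18 genes left, without ASCL2, which has no class, and a median of 0.83, had an adjusted p of 0.051.

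With the replicate number as a replicate block 8170 genes changed, 7750 of them also changed without it. Deviations of same-numbered arrays from their group means correlated at 0.16, 0.059 and 0.078, so the numbers were not taken to pair the arrays, although every array correlated best with its own number, a hint from the data. The filters on mean level, the scale of log2 after adding a constant to the linear value, the intensity trend and the probe set of highest mean were not run, because they need a level finer than the classes. Signal over background is likewise known at most by class, and not at all for the 161 probe sets without one, which include all those of the 12 genes with the largest rise and of MYBL1, PKM and ASCL2.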

Other observations

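All tests below, the gene families included, were chosen after the results were seen, except that of the other splits of the arrays. Genes that share a symbol root, such as the subunits of a complex, were grouped, which gave 341 families of at least 8 genes, of which 20 passed in camera (4 higher, 16 lower) and 0 passed with an estimated correlation, where 19 had an unadjusted p under 0.05 and the smallest adjusted p was 0.742. Directions of the 20 held under the 3 other normalizations of the same arrays, which is no independent support for families picked from these values. In the arrays labelled FAM60A shRNA, 8 of 9 COPS genes, subunits of the COP9 signalosome, fell and 0 rose (adjusted p = 0.013), among them COPS8 (log2 difference -0.93) and COPS7B (-0.44). Of 13 genes with the root ALG, mostly enzymes of N-glycosylation, 10 fell and 1 rose, ALG1L1P (0.52), a pseudogene by its symbol (adjusted p = 0.013), with ALG10B at -1.09 and ALG13 at -0.85. Of 9 EMC genes, subunits of the membrane protein insertion complex of the endoplasmic reticulum, 8 fell and 1 rose (adjusted p = 0.027), with EMC2 at -0.70 and EMC6 at -0.62. Of 12 PSMD genes, subunits and assembly factors of the regulatory particle of the proteasome, 9 fell and 0 rose (adjusted p = 0.026), with PSMD6 at -0.58. Of 18 ATG genes of autophagy, 13 fell and 1 rose (adjusted p = 0.013), with ATG4C (-0.63) and ATG4A (-0.60). Of 48 genes with the root MRPL, mostly mitochondrial ribosomal proteins, 27 fell and 6 rose, including MRPL20-AS1 (0.44), an antisense RNA (adjusted p = 0.045), with MRPL33 at -1.28 and MRPL16 at 0.72.

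The 4 families that rose in the arrays labelled FAM60A shRNA were ARID, KLF, SNHG and TRAF. Of 9 ARID genes, 6 rose and 0 fell (camera, adjusted p = 0.013), among them ARID1A (0.78) and ARID1B (0.77), subunits of the SWI/SNF chromatin remodeller. Of 17 KLF genes, Krueppel-like transcription factors, 10 rose and 1 fell (adjusted p = 0.045), with KLF4 (0.89) and KLF10 (0.73). Of 10 SNHG genes, hosts of small nucleolar RNAs, 6 rose and 1 fell (adjusted p = 0.048), with SNHG8 at 0.77. Of 9 genes with the root TRAF, 6 rose and 1 fell (adjusted p = 0.048), with TRAF1 at 0.73. All of these calls rest on camera's preset correlation. PKM (2.28, 6 probe sets from 1.91 to 2.60) had the largest difference among the glycolysis enzymes and UQCRC2 (1.68) among the respiratory subunits, both higher in the arrays labelled FAM60A shRNA. SRP14, of the signal recognition particle, was higher by 1.98, with 3 probe sets from 1.90 to 2.11.

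SINHCAF was 2.36-fold higher, not lower, in the arrays labelled FAM60A shRNA. The tables argue against inverted signs: single-precision steps grow with the level, and of 918 probe sets with a difference of at least 1 and all values under 1, the step was coarser in the group with higher values in 239 and in the group with lower values in 86, with 593 undecided (95% interval of the share of 239 among the decided 68.4% to 78.3%, exact binomial p = 8.22e-18, which treats probe sets as independent). They also argue against an exchange of 1 array of each group, since the lowest correlation within a group was 0.739 and the highest between groups -0.763. An exchange of the labels of the whole groups, which would give SINHCAF a log2 difference of -1.24, cannot be told apart from an actual rise of SINHCAF in the cells with the shRNA, which was not tested, because no other gene has a direction that the labels fix. A shRNA without effect predicts no difference if the groups differ in the shRNA alone, and the measured one was 1.24 (SE 0.038). Nothing here shows that the groups differ in nothing else, so a shRNA without effect is not excluded.

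Intestinal markers were measured with large differences in arrays labelled as a thyroid cancer line, while the extraction protocol names DLD1. RNA from an intestinal line and RNA from the labelled thyroid line cannot be told apart here. Where the level class is known, a probe set in the class of 8 or more was found for 5 of 17 intestinal genes, 3 of 20 thyroid genes (Fisher's exact p = 0.428 between these lists), and 3 of 32 leukocyte and endothelial genes, 1 of 19 and 2 of 13 (p = 0.106 against the intestinal list), against 6610 of 18036 among all genes (36.6%). The 96 genes left out of the last count had no probe set in that class and an unresolved one, though others of their probe sets may have a lower class. ASCL2, the other intestinal gene, has no class because its difference is too large, and counted as in that class it would give 6 of 18 (Fisher's exact p = 0.26 against the thyroid list, 0.0548 against the leukocyte and endothelial genes). These tests treat genes as independent, and the lists are small. Of single markers, 0 of 9 probe sets of VIM, RET and PAX8 lay in that class, as did 0 of 8 of FN1, 0 of 3 of TG and 0 of 3 of TSHR, and 0 of 3 of VIL1 and 0 of 1 of LGALS4, both intestinal markers. In it were 1 of 1 of CDX2, of KRT20 and of TSPAN8, 2 of 4 of CDH17 and 3 of 3 of the epithelial marker EPCAM. The lowest class holds 16 of 17 control tags without a target. In the lowest class lay 1 of 2 probe sets of VIM, 2 of 3 of RET and 1 of 4 of PAX8. So did 5 of 8 of FN1, 1 of 3 of TG and 3 of 3 of TSHR. Those of VIL1 (3 of 3) and LGALS4 (1 of 1) lay there too, and 0 of CDX2, KRT20, TSPAN8, CDH17 or EPCAM. Other epithelia express KRT20 and TSPAN8 too, and no array of a known TPC-1 or DLD1 culture was analysed to say which classes either line gives. No biological explanation, such as a change of cell identity with the shRNA, was tested.

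The number of genes past the threshold, 8136, was reached by 1 of the 10 splits of the 6 arrays into 3 and 3, the real one. The highest count of the 9 others was 0 in limma, with 159 to 377 genes at an unadjusted p under 0.05, and 10 splits are too few for a share under 0.05.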
